A study of Tetranychus urticae with 11 samples.

How the data were processed

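The series holds 11 arrays with 2 colours from adult females of the two-spotted spider mite, Tetranychus urticae, a plant-feeding arthropod. Mites were kept on bean at 23 °C with 16 h light and 8 h dark. Each experimental range was a row of linked leaf patches, founded by 10 mated females on the core patch, per the labels' protocols. Each array set RNA of females from the end patch of a range, labelled with Cy5, against RNA of females from the core patch, labelled with Cy3. There were 6 arrays of populations called Control and 5 of populations called Mix. The labels do not say what separates Control from Mix, and those names are used as given. RNA was extracted on silica columns and treated with DNase, and 100 ng of it was amplified and labelled with spike-in RNA, per the labels' protocols. The labels call the arrays replicates without saying whether each came from its own experimental range, so p-values measure the spread between these arrays.

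The deposited scanner files give each spot's median signal and median local background as an intensity on a linear scale, with marks for outlier spots, saturation and spots well above background, per the file headers. They were made with Agilent Feature Extraction 10.7.3.1, per the file headers, which also gives a log10 ratio of Cy5 over Cy3 for each spot. The authors' value table of the whole series matched that log10 ratio on every array within 0.00499, so its scale and direction are known, and its column medians lay between -0.000391 and 0. limma is named in the submitters' processing notes without a version or a setting.

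The main values were computed from the deposited median intensities with limma 3.58.1 in R 4.3.3, with version 1.17.8 of the data.table package. The design fixed before the data were examined named mean signals, which the files used here do not hold, and median signals took their place. Background was corrected with normexp and an offset of 50, and each array was normalised by loess with control spots and outlier spots at weight 0. Outlier spots were then set to missing and spots of 1 probe were averaged. Of 56184 probes, 41813 were kept, being well above background in at least 1 channel on at least 5 of the 11 arrays and missing on at most 2. Kept probes of a gene were averaged, which gave 15224 genes, of which 11816 had 3 kept probes and 1369 had 1. The log2 ratio is end over core on every array. No array was dye-swapped, so a dye bias of a probe adds to the ratio of both population types and cancels only in their difference. All Control arrays lay on 1 slide and all Mix arrays on the other, so slide and population type cannot be told apart. No spot of any array was saturated.

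One limma fit over the 11 arrays gave a mean log2 ratio for each population type and the difference Mix minus Control. Tests were two-sided with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. SDs are between arrays of a type. Names came from the array design, which pairs 376 of its 18457 gene IDs with a name, 374 of them measured and 346 of these informative. The reference table used here, of assembly NJAU_TeUrti_SD_1.0, held none of the IDs, so no coordinates are given. Of 30 gene lists fixed before the data were examined, 4 were matched to named genes, by family symbols after the files had been read. They are cytochrome P450s, ABC transporters, carboxylesterases with related hydrolases, and glutathione S-transferases. The other 26 lists were not matched to names and were not tested, among them lists for egg yolk, vision and cell types. A few named genes, such as GABA2 and genes named chitin, would fall under some of them. Lists were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation beside it, and with fry. They were also tested with an exact test that flips the signs of whole arrays within a type, and with an exact permutation of array labels between types.

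Genes were named by a rule fixed before the data were examined. It takes genes past the threshold with the same sign on every array of the type, up to 10 in each direction with an informative name and 2 without. Where fewer than 5 in a direction passed, it takes the 5 of smallest p, said not to have passed, and it adds up to 4 members of each list. Where a gene's core RNA was well above background on no array of a type, its fold is given as a lower bound. The bound sets the end channel's mean against the higher, on each array, of the lowest signal among probes well above background and the probe's own core signal, after normalisation across arrays. It stays open to dye bias.

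Alternatives were no background correction, the deposited log10 ratio and the authors' value table in place of the main values, median centring, scale normalisation, looser and stricter filters, the brightest probe per gene, array weights, other moderation, slide row, a replicate block, other thresholds and each array left out. Alternatives chosen after seeing the data were a correction for position on the slide, tests without the 2 Control arrays of steepest gradient, tests without genes measured by 1 dim probe, and lists of members with complete names. The position correction subtracted on each array a Gaussian local mean of the log2 ratios with an SD of 8 spots. A gene of 1 dim probe has 1 kept probe with a mean log2 signal under 8. Names that hold inc or pseudogene, begin with pABC, or end in p or in p and a digit were read as incomplete. On simulated data with 15224 genes, changes of 0.2, 0.4 and 0.8 on the log2 scale were called for 29.9%, 80.6% and 98.5% of changed genes in Control. The shares were 17.9%, 76.1% and 98.5% in Mix, and 7.46%, 50.7% and 92.4% for the difference. The simulated noise was independent between genes and arrays, without a slide trend or a dye bias, so the shares hold only for such data.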

Results

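Transcript levels of adult female spider mites from the end patch of experimental ranges were set against those of females from the core patch, in 6 Control and 5 Mix arrays. The end patch held females that had moved along the range, and the core patch those that had stayed, according to the series' description. Between 66.8% and 83.7% of spots were well above background for end RNA, and between 68.8% and 86.5% for core RNA. Median signals lay between 292 and 521 for end RNA and between 214 and 447 for core RNA. Spike-in RNA gave slopes of 0.814 to 0.881 for the log ratio, so its ratios were slightly compressed, and for some genes the ratios differed more between the main values and the Feature Extraction log ratio. The number of arrays limits the precision.

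The first comparison asked which transcripts differed between end and core females of Control populations. Most genes with a name on the array belong to 4 families known for detoxification, and those past the test were mostly lower in end females. Of 346 genes with an informative name, 5 were higher and 27 lower. The cytochrome P450 CYP389C3 (tetur05g03410), one of a family of monooxygenases that oxidise small molecules, had a log2 ratio of -0.33 ± 0.18 (SD, n = 6) and a change of -20.6% (adjusted p = 0.046). The esterase gene TuCCE-13 (tetur01g18820) had -0.32 ± 0.15 (SD, n = 6; adjusted p = 0.0059). CYP387A1p1 had -0.30 ± 0.12, CYP392D1 -0.29 ± 0.21, CYP389C6 -0.28 ± 0.071, CYP389C4 -0.26 ± 0.15 and CYP389C2 -0.24 ± 0.10. The esterase gene TuCCE-23 had -0.26 ± 0.16, MSR -0.24 ± 0.15 and the ABC transporter gene pABC-15 -0.21 ± 0.12. The 2 named genes that were higher on all 6 arrays were CYP392D9p at 0.19 ± 0.085 and TuABCF-01, of an ABC subfamily that lacks membrane-spanning parts, at 0.12 ± 0.059. Among genes without a name, tetur24g00510 reached 0.88 ± 0.42, and tetur06g00230 and tetur20g02820 were at -1.01 ± 0.65 and -1.0 ± 1.0. For tetur20g02820 Control 4 and 6 carry the value, at -2.23 and -2.35 against -0.44 to -0.29 on the other 4 arrays. After correction for position on the slide the 2 genes were at -0.86 ± 0.67 and -0.90 ± 0.97 and did not pass (adjusted p = 0.055 and 0.080). tetur33g01160, a gene of 1 dim probe, had a ratio of 0.62 ± 0.11, and 0.64 in Mix. Its core RNA was well above background on 0 of 6 Control arrays and its end RNA on 3. Its lower bound in the main values was 1.38-fold higher in end females, which stays open to dye bias. With the Feature Extraction log ratio its value was 3.07, and at the lowest of the alternatives 0.26. Of the 32 named calls, 5 were at least 2 times as large with that ratio, namely CYP389C2 (-0.56), CYP389C4 (-0.54), CYP389C5 (-0.76), pABC-15 (-0.59) and CCEinc-17 (0.65), and 5 had under 50% of their main ratio.

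Over all 15224 genes, 1533 passed in Control, 685 higher and 848 lower (limma, adjusted p under 0.05), with a median absolute log2 ratio of 0.20 and 25 genes changed at least 1.5-fold. Ratios on the Control arrays also followed the position of spots on the slide, with an SD of 0.065 to 0.18 over blocks of spots against 0.030 to 0.045 on the Mix arrays. After correction for position 537 genes passed, 364 higher and 173 lower, and 382 of these were among the 1533. Of the 27 lower named genes 5 remained, namely TuCCE-13, CYP389C6, CYP389C2, pABC-15 and CYP389C5, and of the 5 higher ones 0. Of the 27 named calls that ended, 6 kept at least 90% of their ratio, namely CYP389C3 (-0.32 ± 0.17), CYP392D1 (-0.31 ± 0.19), CYP389C4 (-0.26 ± 0.16), pABC-18 (-0.21 ± 0.19), CCEinc-17 (0.16 ± 0.12) and ABCCinc-01 (0.18 ± 0.14), and 7 were left with under 50%, namely pABC-30 (-0.080 ± 0.066), TuABCG-17 (-0.081 ± 0.077), TuABCG-08 (-0.039 ± 0.046), CCEinc-03 (-0.057 ± 0.077), ALAS (-0.051 ± 0.085), TuABCF-01 (0.058 ± 0.047) and TuABCA-08 (0.067 ± 0.072). Between these lay CYP387A1p1 (-0.17 ± 0.11), TuCCE-23 (-0.20 ± 0.18), MSR (-0.16 ± 0.13) and CYP392D9p (0.13 ± 0.062) among others. Without Control 3, 4 or 6 the count over all genes was 743, 863 or 744. The balance of directions changed with the scaling. The Feature Extraction log ratio gave 205 higher and 144 lower genes, and median centring gave 557 higher and 2287 lower.

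**Figure D1:**
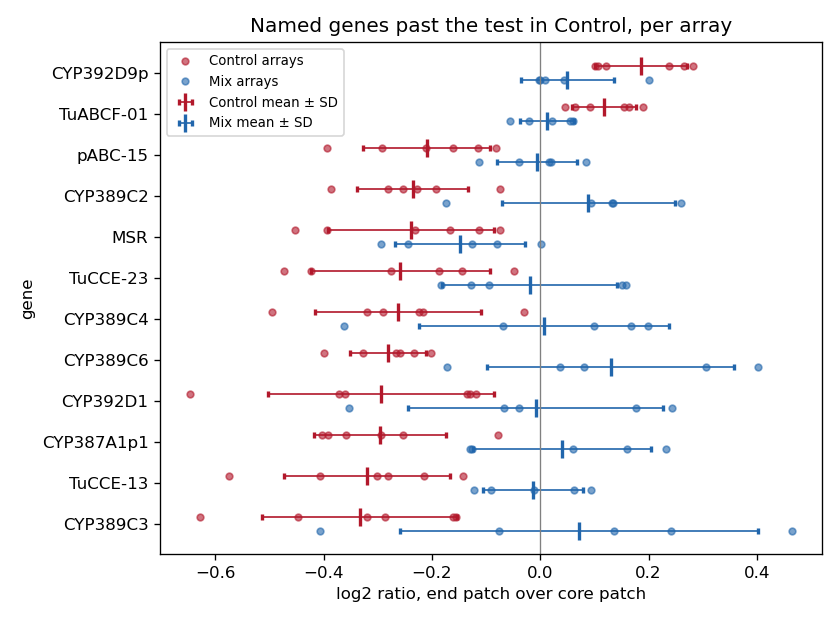
Log2 ratio of end over core (horizontal axis) of 12 of the 25 named genes past the test in Control with the same sign on all 6 arrays, one gene per line. They are the 10 lower ones of largest change and both higher ones. Points are arrays, red for Control and blue for Mix, and bars give the mean ± SD. Control means run from -0.33 for CYP389C3 to 0.19 for CYP392D9p, and Mix values of most of these genes lie on both sides of 0.

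**Figure D2:**
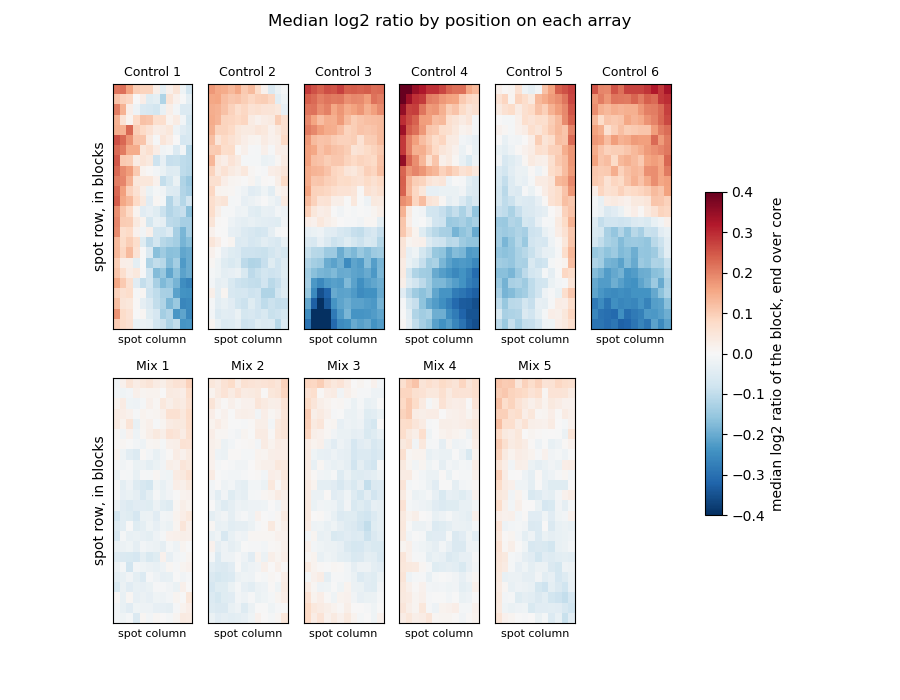
Median log2 ratio of end over core in blocks of neighbouring spots, 24 blocks down and 12 across, drawn at their place on each array, with red above 0 and blue below and values beyond 0.4 drawn at the end of the scale. Control arrays grade across the slide (SD over blocks 0.065 to 0.18), and Mix arrays less so (0.030 to 0.045).

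Family counts of calls are to be read against those over all 15224 genes, 685 higher and 848 lower in Control, and were not tested against that share. By family, cytochrome P450s in Control had 1 higher and 14 lower members in end females of 105 measured. The other 90 did not pass, and adjusted over the list alone 1 was higher and 18 lower. After position correction 0 were higher and 4 lower, as with the Feature Extraction log ratio. Of the 79 members with complete names 0 were higher and 10 lower. The family's mean log2 ratio minus that of other genes was -0.048 ± 0.033 (SD, n = 6), below 0 on 6 of 6 arrays (camera, adjusted p = 0.0090). The call was lost with an estimated correlation (adjusted p = 0.25), and an exact test over sign flips of arrays gave p = 0.031, the smallest possible, and an adjusted p of 0.125 over the 4 lists. After position correction the value was -0.048 (camera, adjusted p = 0.00034, and adjusted p = 0.12 with an estimated correlation). Tested against no change rather than against other genes, the list passed fry (adjusted p = 0.0094), but not after position correction (adjusted p = 0.071). Among ABC transporters, which move substrates across membranes, 3 of 118 were higher and 7 lower, and adjusted over the list alone 3 were higher and 6 lower. The balance was lost after position correction (2 higher, 1 lower) and with the Feature Extraction log ratio (0 higher, 1 lower). Their mean lay at -0.022 ± 0.030 (SD, n = 6) from other genes, below 0 on 4 of 6 arrays (camera, adjusted p = 0.036). It was -0.023 after position correction and -0.029 with the Feature Extraction log ratio (camera, adjusted p = 0.025 in both). The main call was also lost with an estimated correlation (adjusted p = 0.35). With an estimated correlation the other 2 calls were lost too (adjusted p = 0.22 after position correction and 0.40 with Feature Extraction). The main call was not the only one to depend on the correlation used. The main call was lost as well with complete names only, with array weights, and without Control 1, 4 or 5 (-0.011, -0.021 and -0.023). Tested against no change, the ABC transporter list passed fry (adjusted p = 0.0094), but not after position correction (adjusted p = 0.26). Lower members of smallest p were pABC-30 (-0.20 ± 0.091), TuABCG-17 (-0.17 ± 0.074), pABC-15 and pABC-18 (-0.23 ± 0.16), and the pABC names are incomplete ones. Of the 72 ABC transporters with complete names 2 were higher and 3 lower. Of 87 carboxylesterases and related hydrolases, which split esters, 1 was higher and 5 were lower, and adjusted over the list alone 1 was higher and 2 lower. After position correction 0 were higher and 1 lower, and with the Feature Extraction log ratio 1 and 1. CCEinc-17 was at 0.17 ± 0.11 and CCEinc-03 at -0.14 ± 0.099 beside TuCCE-13 and TuCCE-23. The list did not pass (-0.034 ± 0.096, SD, n = 6; adjusted p = 0.096), but did in camera after position correction (adjusted p = 0.033). That call was lost with an estimated correlation (adjusted p = 0.22), and the exact sign-flip test gave p = 0.56. Of 38 glutathione S-transferases, which attach glutathione to reactive compounds, 0 passed, and 0 adjusted over the list alone. Their mean was -0.031 ± 0.049 from other genes (SD, n = 6; adjusted p = 0.30), with TuGSTm04 at -0.24 ± 0.13 and TuGSTo01 at -0.099 ± 0.11, neither past the test.

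**Figure D3:**
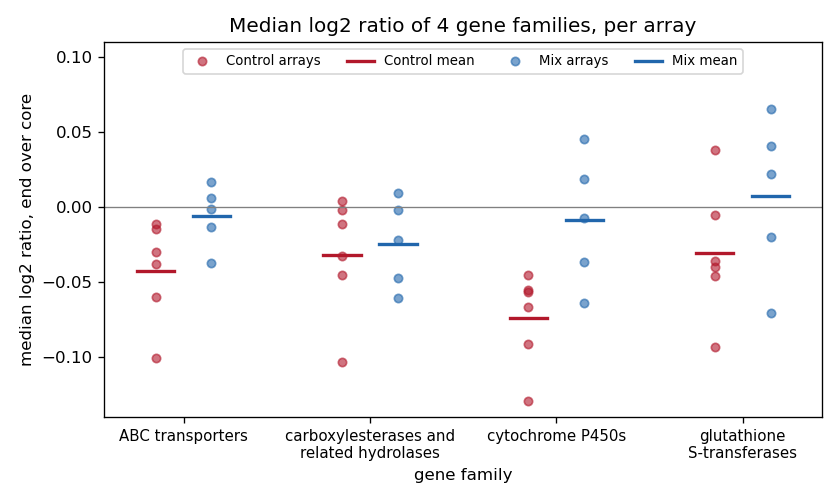
Median log2 ratio of end over core (vertical axis) of the members of 4 gene families on each array, with red points for Control and blue for Mix, and lines for the mean over arrays. The cytochrome P450 median lies below 0 on 6 of 6 Control arrays and on 3 of 5 Mix arrays.

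The second comparison asked the same of Mix populations. No named gene passed, and 0 members of the P450, ABC transporter, esterase and glutathione S-transferase lists were called, also adjusted over each list alone. Their means lay at -0.019 ± 0.084, -0.0092 ± 0.027, -0.017 ± 0.044 and 0.017 ± 0.077 from other genes (SD, n = 5; camera, adjusted p from 0.45 to 0.46). Of named genes, none past the test, those of smallest p with positive values were CYP389C10 (0.15 ± 0.093), TuABCG-06 (0.10 ± 0.063), ABCCinc-01 (0.14 ± 0.063), CCEinc-17 (0.11 ± 0.063) and pABC-33 (0.11 ± 0.11). Those with negative values were ABCAinc-02 (-0.14 ± 0.072), CYP385B1 (-0.18 ± 0.15), CYP392D5p (-0.16 ± 0.042), TuCCE-03 (-0.13 ± 0.097) and ABCCinc-06 (-0.14 ± 0.11). The esterase TuCCE-48 was at -0.11 ± 0.060, and the glutathione S-transferases TuGSTk01 and TuGSTz01 at -0.13 ± 0.057 and 0.071 ± 0.034. Genes without a name made up all 31 calls, 30 higher and 1 lower in end females (limma, adjusted p under 0.05; 1534 genes at an unadjusted p under 0.05). Scale normalisation gave 95 higher and 50 lower genes. tetur05g01270 was at 0.64 ± 0.15, with core RNA well above background on only 1 of 5 arrays, so its size is uncertain (2.38 with the Feature Extraction log ratio). tetur53g00040, with core RNA well above background on 0 of 5 arrays, was at 0.68 ± 0.18. Its lower bound in the main values was 1.42-fold higher, which stays open to dye bias. Its log2 ratio was 2.83 with Feature Extraction and 0.21 at the lowest of the alternatives, and 3 of 27 alternatives ended its call. The lower gene, tetur02g10890, was at -0.45 ± 0.21 (adjusted p = 0.039). Of the 31 genes, 21 also passed in Control, all 21 higher, where independent lists would share 1.35, and both comparisons have the same dye orientation. Without genes of 1 dim probe 0 genes passed, since the adjusted p of the other 12 calls became 0.087 while their ratios stayed the same. Without Mix 1, 2, 3, 4 or 5 the count was 10, 16, 11, 16 or 14.

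The third comparison tested whether the end over core ratio differed between Mix and Control. No gene passed (limma, smallest adjusted p = 0.061, with 2124 genes at an unadjusted p under 0.05). Without Mix 1, 41 did, 33 with a higher and 8 with a lower ratio in Mix. With median centring 788 did, 677 with a higher and 111 with a lower ratio in Mix. Among named genes the smallest p with a higher ratio in Mix belonged to CYP389C10, with a log2 difference of 0.30 ± 0.055 (SE; adjusted p = 0.10), CYP389C6 (0.41 ± 0.092), CYP389C2 (0.32 ± 0.078), pABC-33 (0.27 ± 0.066) and CYP387A1p1 (0.34 ± 0.083). With a lower ratio in Mix they were TuCCE-03 (-0.20 ± 0.056), TuCCE-17 (-0.31 ± 0.088), TuCCE-14-nrl (-0.17 ± 0.053), pABC-10 (-0.24 ± 0.078) and TuCCE-34-nrl (-0.37 ± 0.12), with none of the 10 past the test. Unnamed genes of smallest p were tetur02g02350 (0.41), tetur05g08120 (0.31), tetur22g03001 (-0.40) and tetur03g09770 (-0.57), also not past it. By list, the P450 difference was 0.029 (camera, adjusted p = 0.0997), and past the test after position correction (adjusted p = 0.024). It also passed camera with the Feature Extraction log ratio (adjusted p = 0.014) and with complete names only (adjusted p = 0.021). With an estimated correlation these 2 calls were lost (adjusted p = 0.33 and 0.26). Nor did the difference pass with an estimated correlation in the main values (adjusted p = 0.46) or after position correction (adjusted p = 0.42). An exact permutation of array labels gave an adjusted p of 0.68. Adjusted over the list alone 4 P450s were higher, against 0 over all genes. The differences of glutathione S-transferases, ABC transporters and esterases were 0.048, 0.013 and 0.017 (adjusted p = 0.15, 0.15 and 0.36), with 0 members called over all genes or over each list alone. The P450 list thus passed camera in Control and not in Mix. Its difference between the types passed camera only in some settings and was not shown by the other tests.

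Across genes, which are not independent replicates, the Control and Mix log2 ratios had a Pearson r of 0.163 and a Spearman rho of 0.211, and both share the dye orientation. Of 512 ways to flip the signs of whole arrays, the real one included, 59 gave an absolute r as large. The r was 0.347 with the Feature Extraction log ratio and -0.042 with median centring. Pairs of Control arrays had a median r of 0.205, with a range of -0.012 to 0.349, against 0.047 for pairs of Mix arrays and 0.032 between types. With the Feature Extraction log ratio these medians were 0.206, 0.158 and 0.111, and after position correction 0.169, 0.039 and 0.010.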

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

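The tests of the slide trend, of a dye bias, of probes near background and of subfamilies, the division of the Mix calls by dim probes, and the adjusted threshold for the list without CYP389C were chosen after the results they concern had been seen, while the sign flips, the splits, the signal-matched lists and the list without CYP389C were set before their outcome was known.

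Among 91 groups of values, 3 held an array far from the others, where chance alone gives about 4.55. ABCAinc-02 had a log2 ratio of -0.27 on Mix 2 and of -0.13 to -0.090 on the other Mix arrays. TuCCE-14-nrl had -0.064 on Control 1 and 0.080 to 0.10 on the other Control arrays. On Mix 3, 83.7% of spots were well above background for end RNA, against 68.2% to 70.8% on the other Mix arrays. Of 10 subfamilies, 3 had a mean ratio that differed between Mix and Control in an exact permutation of array labels over 462 splits. The differences were 0.23 for CYP389C, 0.070 for ABCG and 0.095 for GSTd, each with an adjusted p of 0.022. Relative to other genes on the same array, 0 of the 10 passed (adjusted p = 0.097, 0.18 and 0.097). In camera CYP389C passed (adjusted p = 3.9e-06) and ABCG and GSTd did not (0.086 each), and with an estimated correlation 0 of the 10 did (0.18 for CYP389C). In fry, which does not test against other genes, CYP389C, ABCG and GSTd passed (adjusted p = 0.014, 0.042 and 0.019). Slide and population type coincide in all of these tests.

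The 1533 Control calls were found on arrays whose ratios follow the place of a spot on the slide. Among genes with 2 or more called probes, 21.2% had called probes pointing both ways, and 3.75% after position correction, so the slide trend is a likely source of part of the calls. It is not the whole of them, since 382 remained in the same direction. For the 1151 lost ones the mean ratio in the called direction went from 0.21 to 0.13 and the median SD from 0.11 to 0.10. Of these, 95 kept at least 90% of their ratio. With fewer calls the largest unadjusted p that passed fell from 0.0050 to 0.0018 (limma). After correction 233 lost calls had a p still within the earlier limit. How many of these also had a rise in p was not counted. A dye bias shared by all arrays would carry over to Mix. There the 382 genes had 21% of their Control mean, with an SE of 6.27 that covers only the spread between Mix arrays. Choosing genes on Control ratios lowers this share, so a shared dye bias stays open, as the whole cause or a part. A dye bias limited to the Control slide would not carry over, so this comparison cannot test it. Of 32 sign flips of whole arrays 1, the real one, gave as many calls (1533, with 3 at most in the others). After position correction it was also 1 of 32 (537 calls, with 2 at most in the others). That is the smallest share 32 flips can give, and it argues against chance only if the arrays are independent. It excludes neither a slide trend nor a dye bias, and a difference between end and core females stays open.

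Of the 31 Mix calls 61.3% rest on 1 dim probe, against 7.49% of all genes (Fisher's exact test, p = 2.1e-14). In Control, where the dyes run the same way, these 19 genes had 77.7% of their Mix mean, with an SE of 2.08, so dye bias on probes near background may be their source. The other 12 calls, with mean log2 signals of 6.58 to 16.8, had 39.4% of their Mix mean in Control, with an SE of 5.23, narrowly under the 50% set for a shared dye bias as the whole cause, though choosing genes on Mix ratios lowers this share, so it stays open. A difference between end and core females that both population types share would give the same ratios and was not tested, because no array has the dyes swapped. The 16 sign flips are too few for a share under 0.05 (1 of 16 as large, 31 calls, with 1 at most in the others).

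The lower P450 ratios in Control kept their size after position correction (-0.048 before and after; camera, adjusted p = 0.00034, and 0.12 with an estimated correlation; fry, adjusted p = 0.071), which argues against the slide trend as the source of that size. Only 0.09% of 10000 random lists matched on signal level had as low a mean (-0.065, with a mean of -0.020 over such lists), which argues against the signal level of the probes. Without the 11 CYP389C members the log2 shift was -0.034 over 94 genes, with an SE of 0.016 on the log2 scale, and below 0 on 6 of 6 arrays. It had 70.3% of the full list's size, which that SE does not set apart from 50%. Its call changed with the test. In camera the p was 0.032, adjusted 0.064, and the adjusted p after position correction was 0.016. With an estimated correlation the unadjusted p was 0.11, and 0.047 after position correction. Whether the full list's shift rests on the CYP389C members stays open. A shared dye bias cannot be told apart from a difference between end and core, since the shift in Mix was -0.019 with an SE of 0.038. A lower level of P450 transcripts in end females is a hypothesis only.

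For the difference between Mix and Control, 100 splits of the 11 arrays were run. Only 1, the real one, gave as many genes at an unadjusted p under 0.05 (2124, with 1788 at most in the others). This argues against chance for that unadjusted count but does not exclude it. The 100 were drawn from 462, and the remaining splits were not run. At an adjusted p under 0.05 all 100 gave at least the real count of 0 genes, with 1 at most in the others. Slide and population type stay confounded.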

How the results depend on the processing

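The position correction, the tests without the 2 Control arrays of steepest gradient, those without genes of 1 dim probe and those with complete names were chosen after seeing the data. The cause of the changes below was not tested unless named. All other alternatives that were run left a count within 1.5 times its main value.

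The Control count of 1533 became 349 with the Feature Extraction log ratio (260 shared) and 350 with the authors' value table. It became 2844 with median centring, 681 with scale normalisation and 3014 with the brightest probe per gene. The count was 326 with the Control arrays alone, where the Mix arrays add nothing to the estimate of the spread. It was 25 with a 1.5-fold minimum, 2708 at an adjusted p under 0.10 and 7684 with probes as the unit. It was 537 after position correction and 192 without the 2 Control arrays of steepest gradient (177 shared). Leaving out single arrays gave 743 to 1463, with 743, 863 and 744 without Control 3, 4 and 6. The Mix count of 31 became 211 with median centring, 145 with scale normalisation, 20 with no filter, 1 with both channels above background on all arrays, 48 with the brightest probe, 73 with array weights, 0 with trend and robust moderation, 6 with the Mix arrays alone, 5 with a 1.5-fold minimum and 63 at an adjusted p under 0.10. It was 0 without genes of 1 dim probe, where the ratios of the other 12 calls stayed the same (smallest adjusted p = 0.087), 20 without the 2 Control arrays of steepest gradient, and 10 to 32 with single arrays left out. The difference count of 0 became 788 with median centring, where the median difference of all genes was 0.11 against 0.0082 in the main values, 2 with no filter, 11 with the brightest probe, 7 with array weights, 10 with slide row as a covariate, 10 at an adjusted p under 0.10, 2 without genes of 1 dim probe and 0 to 41 with single arrays left out (1 without Control 4 or Mix 5, and 41 without Mix 1).

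Arrays with the same replicate number showed little shared deviation (r = 0.146, -0.058, -0.0078, -0.049 and 0.040 for numbers 1 to 5), and 1 of 5 Mix arrays correlated best with its own number. Samples were therefore not treated as paired by number. A weak correlation cannot exclude such a pairing, and the labels do not say. With the replicate block the counts were 469 in Control (436 shared), 4 in Mix and 0 for the difference.

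Of the 4 lists, 2 passed in Control, and 0 with an estimated correlation, where P450s stay at -0.048 and ABC transporters at -0.022 and only the p changes. With complete names 1 passed (ABC transporters -0.022) and with array weights 1 (ABC transporters -0.012). Leaving out single arrays gave 1 to 3 lists, with shifts of -0.028 to -0.011 for ABC transporters. Under all alternatives run for the lists but the estimated correlation, the P450 shift was past camera's threshold. With single arrays left out it was -0.054 to -0.036. It passed neither the exact sign-flip test (adjusted p = 0.125) nor fry after position correction (adjusted p = 0.071). The lists were not rerun with scale normalisation, the authors' value table, the stricter filter, the brightest probe or trend and robust moderation. Nor were they rerun with slide row, with the arrays of 1 type alone or without genes of 1 dim probe. In Mix, 1 list passed with median centring and 0 to 1 with single arrays left out. For the difference, 1 passed with complete names, 1 with the Feature Extraction log ratio and 1 after position correction, P450s each time. With median centring 3 passed, and 0 to 1 with single arrays left out. Values not past any threshold that changed sign were the ABC transporter shift in Mix with median centring (0.00043), and, with single arrays left out, the P450 shift in Mix (-0.041 to 0.014, positive without Mix 1), the glutathione S-transferase shift in Mix (-0.0017 to 0.046, negative without Mix 1) and the esterase difference (-0.017 to 0.038, negative without Control 5 or Mix 1). The correlation across genes was 0.347 with the Feature Extraction log ratio, 0.347 with the authors' value table and -0.042 with median centring.

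The 32 Control calls with a name and 4 with an ID only were run through the alternatives. Of the 32, 1 changed sign, TuCCE-58, at 0.22 with the brightest probe, which also passed (adjusted p = 0.014). tetur24g00510 passed under all 29 alternatives and TuCCE-13 under all 29 but the 1.5-fold minimum. tetur33g01160, a gene of 1 dim probe, passed under the 27 that could be run for it. These do not include the test without such genes. Of the 32, position correction ended 27, the Feature Extraction log ratio 25, the replicate block 25, scale normalisation 22 and median centring 7. The 8 acaricide target or mitochondrial genes under other observations were not run through them. Among the other named genes that were run, values not past the threshold changed sign in a few. They were CYP392D5p in Mix with median centring (0.010) and TuGSTo01 with the brightest probe (0.083). neverland did so after position correction (0.013) and with single arrays left out (-0.034 to 0.026, positive without Control 2 or 3). CYP315A1 did so with single arrays left out (-0.11 to 0.030, positive without Control 1). CYP307A1 did so with both channels above background on all arrays (0.022), with the brightest probe (0.051), with array weights (0.027), after position correction (0.015) and with single arrays left out (-0.020 to 0.030, positive without Control 1 or 2). Signal over background limits 22 Control calls and 6 Mix calls, whose core RNA was well above background on no array of the type.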

Other observations

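The groups of genes below, and the tests of them, were chosen after their values had been seen. Of the 11 measured members of the CYP389C subfamily of cytochrome P450s, 11 had negative ratios in Control, and 6 of them passed the test over all genes, namely CYP389C2, CYP389C3, CYP389C4, CYP389C5, CYP389C6 and CYP389C10. After position correction 3 passed, CYP389C2, CYP389C5 and CYP389C6, and CYP389C10 went from -0.15 ± 0.062 to -0.086 ± 0.069. The mean log2 ratio of the 11 was -0.19 ± 0.040 (SD, n = 6), below 0 on 6 of 6 Control arrays, and 0.042 ± 0.13 (SD, n = 5) in Mix, below 0 on 1 of 5. Among 10 subfamilies it was the 1 past camera in Control (adjusted p = 6.2e-05), and the call was lost with an estimated correlation (adjusted p = 0.38). After position correction these adjusted p were 8.6e-07 and 0.25. Tested against no change rather than against other genes, CYP389C passed fry (adjusted p = 0.0046), as did ABCG (adjusted p = 0.038). The exact sign-flip test for CYP389C gave p = 0.031, the smallest possible, and an adjusted p of 0.31. The members' correlation was estimated at 0.280, so they are not independent measurements.

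Among enzymes of ecdysteroid synthesis, the pathway of the arthropod moulting hormone, CYP302A1 was lower in Control end females at -0.21 ± 0.13 (SD, n = 6; adjusted p = 0.026), and at -0.18 ± 0.14 after position correction, not past the test (adjusted p = 0.075). The other members were at -0.0061 for neverland, -0.0089 for CYP314A1, -0.058 for CYP315A1 and -0.0011 for CYP307A1, none past the test. ALAS, the entry enzyme of haem synthesis, was at -0.18 ± 0.10 (SD, n = 6; adjusted p = 0.016), and at -0.051 after position correction (adjusted p = 0.43). Of 8 genes known as acaricide targets or mitochondrial complex members, 0 were called in any comparison. They were the sodium channel VGSC, the ryanodine receptor RyR, the chloride channel GABA2, ACCase, PSST, TYKY, Rieske and Cytc1. Of these RyR had the smallest adjusted p in Control, at 0.076.

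A hypothesis is that genes with consecutive ID numbers share their change between end and core. Over 14901 pairs the log2 ratios correlated with r = 0.152 in Control after position correction, against 0.028 at most in 1000 permutations of genes (p = 0.001, the smallest they can give). Without position correction r was 0.130 in Control, 0.108 in Mix and 0.161 for the difference. Without pairs of the same named family these were 0.130, 0.107 and 0.161, and 0.152 in Control after position correction. The values are consistent with a shared change of neighbouring genes, if consecutive numbers mark neighbours on the genome. Probes that bind several similar copies could give the same correlation for unnamed families, and this was not tested.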
